A study of Mus musculus with 9 samples.

How the data were processed

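Mouse lymph node cells were profiled by 10x 3' single-cell RNA sequencing: live YFP+ cells sorted from celiac, duodenal and liver nodes of CD11c-YFP mice, 3 replicates per node, with 10 mice pooled per library. The submitters' processing notes and matrix headers give Cell Ranger 3.0.0 and the mm10 genome. The deposited matrices hold raw UMI counts per gene and barcode over 32285 genes, with the authors' cell calling already applied by rules the labels do not state. Matrices of 7 of the 9 libraries were analysed. The authors also deposited marker tables for 8 clusters, with log2 fold changes and p-values over cells, and a table of mean expression per cluster scaled to 10000; the cells behind these tables are not named, and their values are given as deposited without a test.

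Barcodes were kept with at least 500 genes, at least 1000 UMIs and at most 10% of UMIs from mitochondrial genes, and doublets called by Scrublet were removed in each library. Scrublet called 1, 292 and 1 doublets in celiac replicates 1, 2 and 3, 4, 0 and 2 in duodenal replicates 1, 2 and 3, and 661 in liver replicate 3, so its own threshold failed in 5 of 7 libraries. Total UMIs per library ranged from 27237000 to 59062000. Counts were scaled to 10000 per cell and log transformed, 2000 variable genes were chosen with library as the batch, and 30 principal components without integration, 15 neighbours and Leiden clustering at resolution 1 (seed 0) gave 28 clusters. These steps used Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

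Clusters were named from 16 fixed marker lists. A list had to reach a score of at least 0.35, with the next unrelated list at no more than 0.6 of it, and at least 3 of its genes in more than 5% of cells; otherwise the cluster stayed unnamed and was left out of the comparisons. These naming thresholds and the pairs of related classes were set while the clustering was in view, and the alternatives use the maxima of the main clustering, a change made after the result at resolution 2 was seen. Each name was checked against the cluster's 10 leading genes. The check first used a fold pseudocount of 0.1, and 1 replaced it after clusters 1, 4 and 11 failed.

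Counts were summed over the cells of a class in each library, so the library is the replicate. A library with fewer than 20 cells of a class was left out, and a class needed at least 2 libraries in each group. Summed UMIs of migratory cDC ranged from 305220 to 13657000 per library. Celiac and duodenal libraries were compared by edgeR's quasi-likelihood F-test (edgeR 4.0.16 in R 4.3.3, TMM scaling, filterByExpr), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM are summed UMI counts scaled to a common library size by TMM. The difference between the effects in migratory cDC1-like and cDC2-like cells was tested as an interaction with library as a block. Liver replicate 3 was set against the mean of the celiac and duodenal groups in a fit of 7 libraries. DESeq2 1.42.0 was the other tool.

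Genes to name were chosen by a rule: among genes past the threshold whose celiac and duodenal libraries did not overlap, the 12 largest fold changes each way in migratory cDC and the 5 largest each way in each other cDC class, with predicted and immunoglobulin segment genes counted only. Where fewer than 6 passed, genes of the smallest unadjusted p filled up. The rule took the 10 largest each way in the liver contrast among genes outside the range of the other 6 libraries, the 4 smallest adjusted p in the interaction, up to 4 members of each list past the threshold or else the 2 of smallest p, and 7 fixed markers. The genes of largest effect are given in full and the rest where they bear on a comparison. The labels do not say that replicate numbers pair the libraries, and they were not treated as pairs. Gene lists, 31 in all, were tested with fry in limma 3.58.1 where at least 3 genes were measured, with camera as the alternative; both are two-sided. Fry's test asks whether a list's genes move one way on balance, its mixed form whether they change in either direction, and neither compares the list with other genes. Coordinates are from the GENCODE annotation of GRCm38.

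Shares of cell classes were compared by a two-sided exact permutation test, whose smallest p for 3 against 3 libraries is 0.1, with Benjamini-Hochberg adjustment over the classes. Shares of a single library carry exact 95% binomial (Clopper-Pearson) intervals, and ratios with few UMIs carry exact counting intervals; both cover counting error only. A gene with 0 UMIs in one group is given as a lower bound against 3 counts over that group.

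The tests, sample groups, marker lists, gene lists, naming rule for genes, filters and the first set of alternative settings were chosen before the data were examined. That set held other scaling (RLE), DESeq2, no filter on low counts, a replicate block, all 7 libraries in one fit, resolutions 0.5 and 2, doublets kept, looser cell filters (300 genes, 500 UMIs, 20% mitochondrial), a 5% mitochondrial limit, thinning of the summed counts to the smallest library, and leaving out each library in turn. Added afterwards were the removal of both duodenal replicates 2 and 3, a fixed doublet rate of 0.8% per 1000 cells, single clusters in place of classes, liver against celiac libraries alone, and the removal of barcodes with at least 10 acinar or red cell UMIs or of each gene's highest barcode. Liver genes chosen after their values were seen were first picked without each gene's highest barcode, and then, once that list was seen, as those with under 10% of UMIs in 1 barcode.

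The model was tested on simulated data made from these libraries with 200 changed genes. It recovered 87.2%, 90.6%, 94.8% and 90.6% of 4-fold differences and 37.5%, 21.4%, 47.4% and 42.1% of 2-fold differences in migratory cDC1-like, migratory cDC2-like, resident cDC1-like and resident cDC2-like cells. For the liver contrast it recovered 85.9% and 26.3%, and for the interaction 74% and 27.6%. Among unchanged genes it called 11, 1, 7 and 7 in the 4 classes in that order, 7 in the liver contrast and 3 in the interaction. The simulated counts held no free RNA and no mix of clusters, so recovery in the real libraries can be lower. Figures were drawn with matplotlib 3.10.9. A few results of single genes are not reported here.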

Results

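The series compared dendritic cells of the lymph nodes that drain the pancreas, the gut and the liver, to ask how these organs share draining nodes. Live YFP+ cells were sorted from celiac, duodenal and liver-draining nodes of CD11c-YFP mice, a reporter line that marks cells using the Itgax (CD11c) promoter, and profiled by 3' droplet single-cell RNA sequencing with unique molecular identifiers (UMIs). Each node type had 3 biological replicates, each a pool of 10 mice aged 6 to 8 weeks. Count matrices of 7 libraries were compared: 3 celiac, 3 duodenal and liver replicate 3. Liver replicates 1 and 2 were not analysed here beyond their 10550 and 11396 listed barcodes.

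The 7 libraries held 27237000 to 59062000 UMIs each, rounded to 5 digits. Celiac replicates 1, 2 and 3 had 9320, 8740 and 3241 barcodes with medians of 4289, 5605 and 8665 UMIs per barcode. Duodenal replicates 1, 2 and 3 had 9097, 2336 and 3882 barcodes with medians of 4454, 6142 and 7113 UMIs, and liver replicate 3 had 12696 barcodes with a median of 3395 UMIs. After filtering, 7374, 7722, 2781, 8093, 1709, 3870 and 11354 cells were kept in that order. They formed 28 clusters, named from fixed marker lists.

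Conventional dendritic cells (cDC) are split by function into cDC1, which cross-present antigen to CD8 T cells, and cDC2, which mainly prime CD4 T cells, and by origin into migratory cells arriving from tissue with Ccr7 and residents of the node. Migratory cDC1-like cells (clusters 4 and 12), migratory cDC2-like cells (clusters 6 and 15), resident cDC1-like cells (cluster 13) and resident cDC2-like cells (cluster 1) were compared between nodes. Migratory cDC1-like cluster 4 and resident cDC2-like cluster 1 kept their names under only 1 of the 2 definitions of the name check that were tried. A name passed if the 10 leading genes held no fewer markers of its class than of any other list. Cluster 1 had 0 of its own markers there under both definitions, and passed under 1 because other lists had 0 as well. Its name rests on its list score of 0.384, not on its leading genes. Cluster 14, named RORgt+ for its transcription factor, failed under the definition used and was not compared. Cluster 26 took 94.15% of its cells from duodenal replicate 3 and cluster 27 took 86.7% from duodenal replicate 2.

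Duodenal replicates 2 and 3 carried B cell RNA in more of their cells than the other 5 libraries. The immunoglobulin light chain gene Igkc, made by B cells and plasma cells, was seen in 99.3% and 100% of their cells, against 79.6%, 67.6% and 50.3% in celiac replicates 1, 2 and 3, 62.3% in duodenal replicate 1 and 49.3% in liver replicate 3. Among migratory cDC, which should lack it, Igkc reached 96.9% and 100% of cells in duodenal replicates 2 and 3, against 26.8% to 71.8% in the other 5 libraries. The B cell gene Cd79a and the T cell gene Cd3e shared cells 1.13 and 1.09 times as often as independence gives in those replicates, against 0.23 to 0.42 times elsewhere. Fscn1, a gene of migratory cDC, was seen in 79.6% and 90.7% of all cells of these replicates, against 15.9% to 41.6% elsewhere, and shared cells with Cd79a 1.04 and 1.02 times as often as independence gives, against 0.17 to 0.51 times. In the same replicates 60.2% and 95.1% of cells stayed without a class, against 1.2% to 5.77% in the other 5. They added only 130 and 29 migratory cDC to the duodenal group, beside 726 from duodenal replicate 1, while celiac replicates gave 1093, 2334 and 778 and liver replicate 3 gave 4278.

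Migratory cDC2-like cells made up 28.5% ± 2.63 (SD, n = 3) of the cDC-like cells in celiac and 27.7% ± 2.95 (n = 3) in duodenal libraries (exact permutation test, two-sided, p = 0.7). The denominator was the 4 cDC-like classes plus cluster 14. Migratory cDC1-like cells made up 28.7% ± 6.27 and 20.8% ± 4.79 of it (exact permutation p = 0.3), resident cDC1-like cells 15.8% ± 4.01 and 19.8% ± 3.67 (exact permutation p = 0.3), and resident cDC2-like cells 23.4% ± 5.13 and 21.8% ± 6.55 (exact permutation p = 0.8). All migratory cDC together came to 57.1% ± 7.40 and 48.5% ± 7.27 (exact permutation p = 0.3). With replicate numbers ignored, no such share differed by more than the replicate spread allows to be told. An exact p below 0.1 cannot come from 3 against 3 libraries. All migratory cDC came to 60.79%, 62.01% and 48.625% in celiac replicates 1, 2 and 3, and to 50.95%, 54.17% and 40.28% in duodenal ones. By replicate number they and migratory cDC1-like cells were higher in each celiac library, and resident cDC1-like cells lower. Migratory and resident cDC2-like cells went both ways. The labels do not say that replicate numbers pair the libraries, so this was not tested. In liver replicate 3, 73.4% of cDC-like cells were migratory (exact 95% binomial interval 72.3 to 74.6) and 46.6% were migratory cDC2-like (45.3 to 47.9), both above each of the other 6 libraries. These are shares among sorted YFP+ cells.

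**Figure D1:**
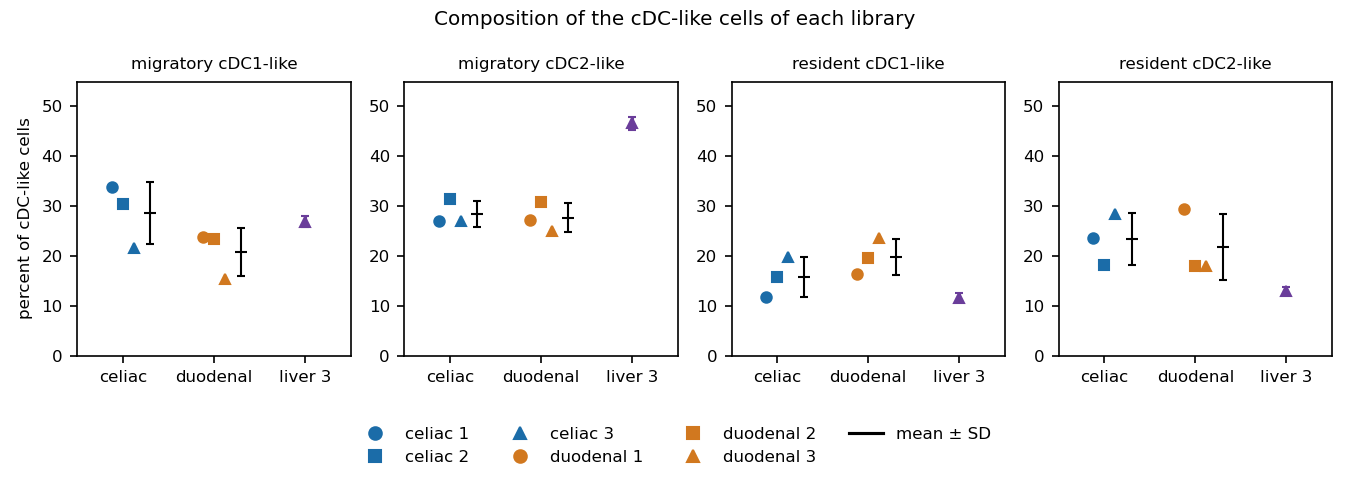
Percent of cDC-like cells in each of the 4 cDC classes, for celiac and duodenal libraries (points are libraries, bars the mean and SD) and for liver replicate 3 (point with its exact 95% interval). Migratory cDC2-like cells average 28.5% in celiac and 27.7% in duodenal libraries, and reach 46.6% in liver replicate 3.

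Over all kept cells, migratory cDC averaged 24.3% ± 8.32 in celiac and 5.78% ± 4.41 in duodenal libraries (exact permutation p = 0.1, the smallest possible; adjusted p = 0.214), and 37.7% in liver replicate 3 (36.8 to 38.6). Cells left without a class made up 2.30% ± 1.51 of celiac and 53.7% ± 45.0 of duodenal libraries and enter the denominator. Unnamed cluster 22 held 670 cells of duodenal replicate 2 and 164 of duodenal replicate 3. By the definition used, its leading genes included Fscn1 and Ccr7 of migratory cDC, so the duodenal share may be too low. Whether these are migratory cDC or other cells with free cDC RNA was not tested. Duodenal replicate 1, with only 5.77% of cells without a class, had 8.97% migratory cDC, below the 14.8% to 30.2% of the celiac libraries. Cells without a class were the only group past the threshold in edgeR's quasi-likelihood test on cell counts (adjusted p = 0.0384).

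Migratory cDC of celiac nodes expressed more Muc1, Il2ra and Kctd12, and less Smox, Pla2g7, Lyz2 and Cd14, than those of duodenal nodes. Muc1 (chromosome 3, 89229057 to 89233381, GRCm38), a membrane mucin of epithelia that haematopoietic cells also make, averaged 5.20 ± 0.327 CPM (SD, n = 3) in celiac and 0.0712 ± 0.123 (n = 3) in duodenal libraries, a log2 fold change of 4.84 (SE 0.74, adjusted p = 0.0163). It rested on 140 UMIs in 118 celiac cells against 1 duodenal UMI, in replicate 1, without which the fitted value came to 7.90; the pooled ratio was 32.4 (95% counting interval 5.72 to 1289). Il2ra (chromosome 2, 11642807 to 11693193), the alpha chain of the interleukin 2 receptor (CD25), averaged 32.1 ± 5.54 and 10.2 ± 2.87 CPM (log2 fold change 1.55, SE 0.27, adjusted p = 0.0266). Kctd12 (chromosome 14, 102976581 to 102982637), a potassium channel tetramerisation domain protein, averaged 183 ± 14.7 and 75.0 ± 13.9 CPM (log2 fold change 1.26, SE 0.24, adjusted p = 0.0346).

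Smox (chromosome 2, 131491496 to 131525922), the spermine oxidase that breaks down polyamines, had the smallest p of the genes lower in celiac nodes, with 6.02 ± 0.561 CPM against 22.5 ± 3.15 (log2 fold change -1.88, SE 0.25, adjusted p = 0.0117). Pla2g7 (chromosome 17, 43568098 to 43612201), the secreted hydrolase of platelet-activating factor, averaged 65.7 ± 21.2 and 208 ± 102 CPM (log2 fold change -1.69, adjusted p = 0.0346). It is a leading gene of cluster 15 by 1 of the 2 definitions of the name check. That cluster held 333 of 726, 69 of 130 and 15 of 29 migratory cDC of duodenal replicates 1, 2 and 3. In celiac replicates 1, 2 and 3 it held 154 of 1093, 493 of 2334 and 144 of 778, so a different mix of clusters is not excluded. Lyz2, the lysozyme of myeloid cells, averaged 35.9 ± 8.93 and 145 ± 67.5 CPM (log2 fold change -2.02, adjusted p = 0.0163), and 13.8% of its duodenal UMIs came from 1 barcode. Cd14, the lipopolysaccharide co-receptor, averaged 1.87 ± 0.248 and 9.16 ± 4.94 CPM (log2 fold change -2.52, adjusted p = 0.0133), with 18.6% of duodenal UMIs in 1 barcode. Ido1 (chromosome 8, 24584136 to 24597009), the tryptophan-degrading enzyme of tolerogenic dendritic cells, averaged 10.5 ± 1.93 and 32.5 ± 19.8 CPM (log2 fold change -1.83, SE 0.29, adjusted p = 0.0163), with overlapping library values. Gramd3, Trf, Pkp3, Mir99ahg and Adam11 were also higher in celiac nodes, with log2 fold changes of 1.17 to 2.43, and Cyp4f18, Syngr3, Glycam1 and Cd300a were lower by log2 fold changes of -2.49 to -1.62. Glycam1, a mucin-like ligand of high endothelial venules, had 18% of its duodenal UMIs in 1 barcode.

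**Figure D2:**
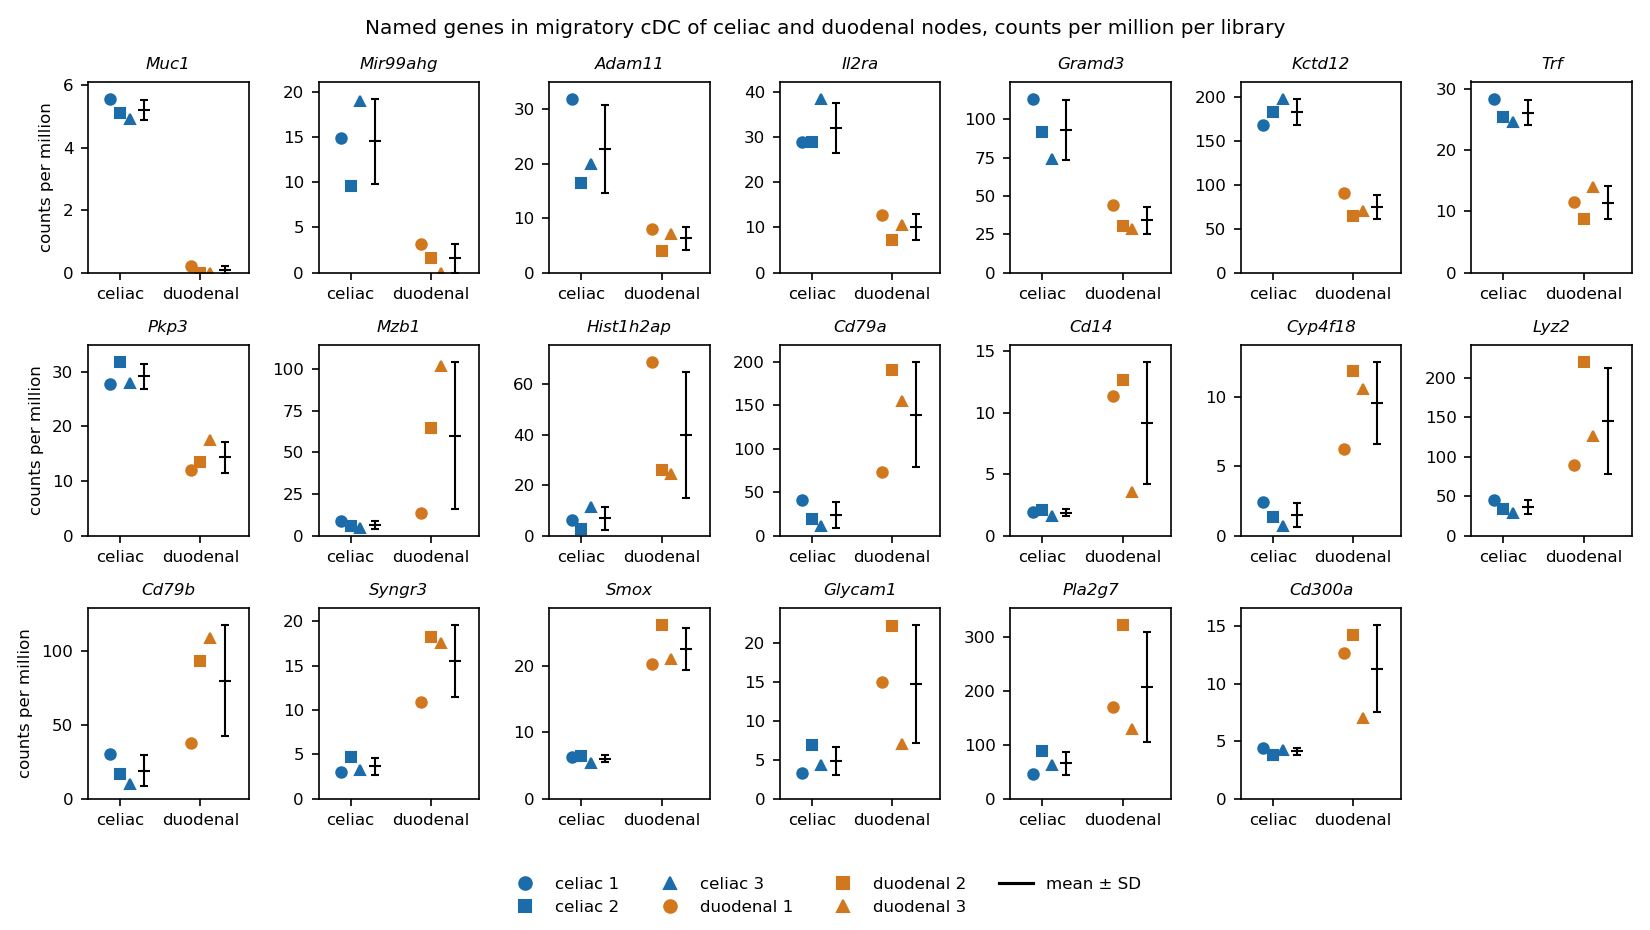
CPM of 20 named genes in migratory cDC, each panel on its own linear axis from 0, for each celiac and duodenal library (points) with the mean and SD of each group. Muc1 averages 5.20 CPM in celiac and 0.0712 CPM in duodenal libraries, and Smox 6.02 and 22.5 CPM.

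B cell and plasma cell genes were lower in celiac migratory cDC, and 4 of the 5 named ones no longer passed once the duodenal libraries rich in B cell RNA were left out. Cd79a (log2 fold change -2.52), Cd79b (-1.92) and Mzb1 (-2.86) all passed, as did the immunoglobulin genes Igha (-5.32) and Jchain (-3.80, with 16.5% of duodenal UMIs in 1 barcode). Without duodenal replicates 2 and 3, Cd79b came to -0.98, Mzb1 to -1.13, Igha to -1.05 and Jchain to -0.18, none past the threshold, while Cd79a passed at -1.63. Muc1 kept 4.51 and stayed past the threshold in that setting, while Adam11 and Cyp4f18 did not.

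In all, 44 of 10304 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 10 higher and 34 lower in celiac migratory cDC, with 1070 at an unadjusted p under 0.05. The libraries of both groups did not overlap for 39 of the 44, and for 17.8% of all genes tested, where chance gives 10%. DESeq2 called 55, 30 of them shared. The count moved to 2 without celiac replicate 2, to 21 without celiac replicate 3, to 1252 without duodenal replicate 1 and to 12 without duodenal replicate 2. Leaving out duodenal replicates 2 and 3 together gave 136 genes, 35 of them among the 44. Clustering at resolution 0.5 gave 5, a 5% mitochondrial limit 9 and thinning to the smallest library 2, all of them among the 44. On simulated data of these sizes, without free RNA, the test recovered 95.8% of 4-fold and 40.2% of 2-fold differences, with 4 false calls.

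Gut cDC imprint intestinal homing on T cells with retinoic acid. The list of retinoic acid synthesis and vitamin A handling genes came to a median log2 fold change of -0.52 in celiac migratory cDC. Only 3 of its 10 listed genes were measured, and not all of them make retinoic acid. Dhrs3, a retinal reductase, had -0.98 (51.4 ± 4.56 and 104 ± 14.3 CPM, adjusted p = 0.0763) and was the only list member adjusted over the list alone. Aldh1a2, which makes retinoic acid, had -0.52 (221 ± 67.3 and 316 ± 77.5 CPM, adjusted p = 0.549). The list had the smallest fry p of the lists tested (adjusted p = 0.0957) and camera with an estimated correlation gave an adjusted p of 0.374.

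Antigen presentation by MHC class II was on the lower side in celiac migratory cDC, with 0 of 16 genes higher, a median log2 fold change of -0.65 and 2 genes past the threshold adjusted over the list alone (fry adjusted p = 0.201). H2-Ob, a chaperone of class II loading, came closest over all genes with -1.30 (adjusted p = 0.0527). B cells make class II genes as well, and the B cell list had a median of -1.64 with 0 of 10 genes higher in the same libraries. Cholesterol synthesis genes of the SREBP2 program lay on the other side in 15 of 18 cases, with a median of 0.18 (fry adjusted p = 0.504) and 0 adjusted over the list alone; Hmgcs1 had 0.62. Maturation and migration genes had 9 of 16 higher and a median of 0.05 (fry adjusted p = 0.660), with 0 adjusted over the list alone, and the type I interferon response had 10 of 19 higher and a median of 0.02, again with 0 adjusted over the list alone. TGF-beta activation genes, which help turn T cells regulatory, had 5 of 9 higher and a median of 0.27 (0 adjusted over the list alone), with Itgb8 at 0.64 and Tgfbr1 at 0.63. Of 13 checkpoint and tolerance genes 6 were higher, Ido1 passed over all genes, and 2 passed adjusted over the list alone. Of 8 homing and chemotaxis receptors 4 were higher, with a median of -0.03 and 0 adjusted over the list alone.

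Of the 23 lists measured in migratory cDC, 0 passed in fry after adjustment, with 5 at an unadjusted p under 0.05, and camera with an estimated correlation gave 0 and 3. The fry test for a change in either direction called 1 list, NF-kappaB and inflammatory cytokines (adjusted p = 0.0163), in which 10 of 18 genes were higher and 4 passed adjusted over the list alone. The B cell list, with 0 of 10 genes higher, had 2 past the threshold over all genes and 8 adjusted over the list alone. Ccr7 (-0.24), the chemokine receptor that brings cDC to the node, did not pass. Neither did the lineage markers Xcr1 (0.36) and Sirpa (-0.25), the checkpoint gene Cd274 (0.10) or Itgax (-0.03).

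Migratory cDC2-like cells of celiac nodes expressed more S100a4, Cxcl1 and Tnfsf9, and less Ido1, Smox and Lyz2, than those of duodenal nodes. S100a4 (chromosome 3, 90603771 to 90606045), a calcium-binding protein of motile cells, averaged 1185 ± 156 CPM (SD, n = 3) in celiac and 224 ± 20.3 (n = 2) in duodenal libraries (log2 fold change 2.40, SE 0.30, adjusted p = 0.0140). Ido1 averaged 17.3 ± 3.67 and 71.0 ± 13 CPM (log2 fold change -1.99, SE 0.26, adjusted p = 0.0140), and Smox 8.02 ± 0.150 and 33.6 ± 6.23 CPM (log2 fold change -2.01, SE 0.26, adjusted p = 0.0140). Cxcl1 (chromosome 5, 90891241 to 90893115), a neutrophil chemokine, averaged 63.9 ± 26.4 and 8.76 ± 4.43 CPM (log2 fold change 2.67, SE 0.45, adjusted p = 0.0437). Tnfsf9, the ligand of the T cell co-stimulator 4-1BB, averaged 100.4 ± 23.1 and 28.9 ± 2.89 CPM (log2 fold change 1.82, adjusted p = 0.0437).

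Of 9473 genes in migratory cDC2-like cells 15 passed, 8 higher and 7 lower, with 866 at an unadjusted p under 0.05. Duodenal replicate 3 had too few cells, so the comparison set 3 libraries against 2. Mir99ahg, AA467197 and Capsl were also higher (log2 fold changes 1.93 to 2.46), and Hist1h2ap (-3.12), Lyz2 (-2.18) and Rasl11a (-2.02) lower, with 16.7% and 18.1% of the duodenal UMIs of Lyz2 and Rasl11a in 1 barcode. The class joins cluster 6, filled mainly by celiac and liver cells, and cluster 15, filled by both groups. Cluster 6 held 331 of 485, 693 of 1186 and 287 of 431 cells of the class in celiac replicates 1, 2 and 3. In duodenal replicates 1 and 2 it held 54 of 387 and 5 of 74. Cluster 15 alone called 0 genes and cluster 6 held too few duodenal cells to test. A different mix of clusters is therefore not excluded for the genes named in this class. The count was 0 without celiac replicate 1, 5 without celiac replicate 3, 409 without duodenal replicate 1 and 204 without duodenal replicate 2. DESeq2 called 62 genes.

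Lists tested in migratory cDC2-like cells gave 0 of 23 past the threshold in fry, with 2 at an unadjusted p under 0.05, and 0 in camera, with 0 at an unadjusted p under 0.05. In either direction fry called 6 of them: checkpoint genes, maturation and migration, type I interferon, interferon gamma, NF-kappaB and the type 2 cytokine response (adjusted p = 0.0152 each), with 3, 1, 2, 1, 3 and 2 genes past the threshold adjusted over the list alone. The B cell list had a median of -1.73 with 0 of 9 genes higher and 8 adjusted over the list alone in the same cells, and immunoglobulin heavy chain genes a median of -1.62 with 5 adjusted over the list alone. Ccl17, a chemokine of cDC2 for CCR4+ T cells, had 1.19 (adjusted p = 0.105). Cholesterol synthesis genes were on the higher side in 16 of 18 cases with a median of 0.24, without passing.

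Migratory cDC1-like cells of celiac nodes expressed less Ccl4, Pla2g7 and Hilpda than those of duodenal nodes. Ccl4, a chemokine that draws T cells, averaged 5.18 ± 2.03 CPM (SD, n = 3) in celiac and 25.7 ± 3.23 (n = 2) in duodenal libraries (log2 fold change -2.21, SE 0.35, adjusted p = 0.0386), with 62.9% of the duodenal UMIs in 1 barcode. Pla2g7 averaged 14.4 ± 5.26 and 62.9 ± 29.8 CPM (log2 fold change -1.97, SE 0.34, adjusted p = 0.0435). Hilpda, a hypoxia-induced lipid droplet protein, averaged 3.24 ± 0.501 and 15.4 ± 0.717 CPM (log2 fold change -2.27, adjusted p = 0.0391), with 60% of its duodenal UMIs in 1 barcode. Aldh1a2 had -0.96 (295 ± 125 and 576 ± 264 CPM, adjusted p = 0.473). The class joins clusters 4 and 12 in proportions that differ between libraries, and Aldh1a2 is among the leading genes of cluster 12, so its value does not tell a change within cells from another mix.

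In migratory cDC1-like cells 7 of 9473 genes passed, 0 higher and 7 lower, with 842 at an unadjusted p under 0.05; the others were Hist2h2aa1 (-4.01), Hist1h2ap (-2.90), Bloc1s1 (-1.82) and the predicted gene Gm10260. DESeq2 called 26 genes, and cluster 4 alone called 0. The count came to 806 without duodenal replicate 1, and to between 5 and 10 without any other library. Of 23 lists 0 passed in fry or in camera, with 1 and 0 at an unadjusted p under 0.05. MHC class II genes had 1 of 16 higher, a median of -0.67 and 5 past the threshold adjusted over the list alone (fry adjusted p = 0.339). The B cell list had 0 of 9 higher, a median of -1.14 and 7 adjusted over the list alone in the same cells.

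In B cell-like cells celiac libraries differed from duodenal replicate 1 by log2 values of -3.24 for Hist1h2ap, -2.57 for Hist2h2aa1, -1.89 for Bloc1s1, -1.78 for Gstp1 and -1.54 for Wdr89. Histone genes and Gstp1 have near-identical copies that can share reads, so calls of these genes in cDC are uncertain.

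For Tnfsf9, Fabp5, Ccrl2 and Tnfaip2 the difference between celiac and duodenal nodes was not the same in migratory cDC1-like as in cDC2-like cells. Tnfsf9 (chromosome 17, 57105325 to 57107757) averaged 58.6 ± 2.89 CPM in celiac and 119 ± 47.6 in duodenal cDC1-like cells, against 100.4 ± 23.1 and 28.9 ± 2.89 in cDC2-like cells, a difference between the log2 effects of -2.60 (SE 0.24, adjusted p = 3.3e-05; SD, n = 3 and 2). Fabp5 (chromosome 3, 10012548 to 10016607), a fatty acid-binding protein, averaged 162 ± 5.73 and 224 ± 86.3 CPM in cDC1-like cells, and 2430 ± 438 and 1067 ± 534 in cDC2-like cells (difference -1.69, SE 0.17, adjusted p = 5.8e-05). Ccrl2 (chromosome 9, 111054486 to 111057519), an atypical receptor that presents chemerin, averaged 181 ± 17.9 and 132 ± 57.2 CPM in cDC1-like cells, and 196 ± 23.4 and 371 ± 167 in cDC2-like cells (difference 1.40, SE 0.16, adjusted p = 0.000268). Tnfaip2, a gene induced by tumour necrosis factor, averaged 123 ± 14.4 and 75.5 ± 48.8 CPM in cDC1-like cells, and 96.2 ± 9.37 and 162 ± 49.7 in cDC2-like cells (difference 1.39, SE 0.19, adjusted p = 0.00257).

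The test of these differences, with library as a block, called 58 of 10089 genes, 26 with the larger celiac effect in cDC1-like cells and 32 in cDC2-like cells, and 1242 at an unadjusted p under 0.05. The count was 37 without celiac replicate 1, 32 without celiac replicate 2 and 101 without duodenal replicate 2. Most celiac cDC2-like cells lay in cluster 6, of which Fabp5 is the leading gene, and most duodenal ones in cluster 15, so a different mix of clusters is not excluded. Of these 4 genes, Tnfsf9 alone also passed within a class, in migratory cDC2-like cells.

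**Figure D3:**
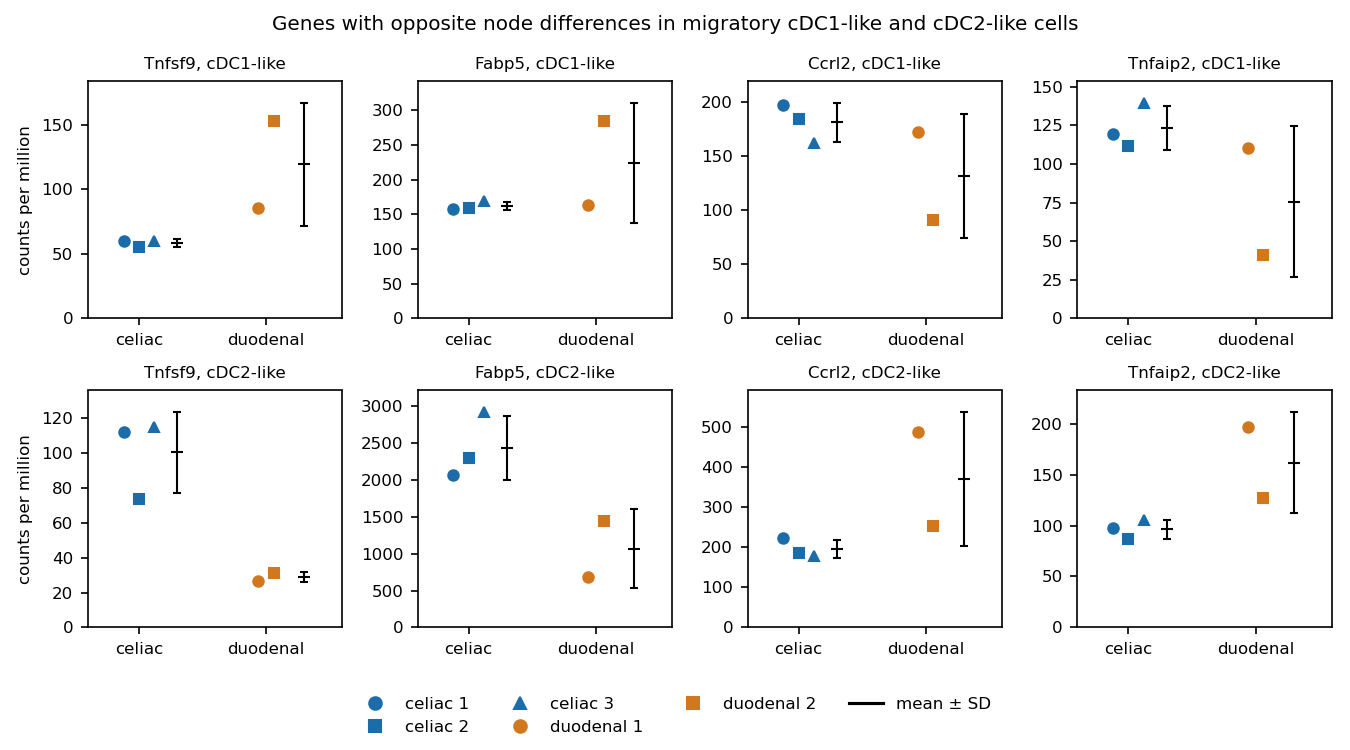
CPM of Tnfsf9, Fabp5, Ccrl2 and Tnfaip2 in migratory cDC1-like and cDC2-like cells, for each of 3 celiac and 2 duodenal libraries (points) with the mean and SD. Tnfsf9 averages 58.6 CPM in celiac and 119 CPM in duodenal cDC1-like cells, and 100.4 and 28.9 CPM in cDC2-like cells.

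Resident cDC1-like cells of celiac nodes had less Mzb1 and Gstp1 than those of duodenal nodes. Mzb1, a chaperone of plasma cells, averaged 4.09 ± 3.21 CPM (SD, n = 3) in celiac and 35.2 ± 10.5 (n = 2) in duodenal libraries (log2 fold change -3.15, SE 0.45, adjusted p = 0.0439), with 53.5% of the duodenal UMIs in 1 barcode. Gstp1, a glutathione transferase, averaged 16.3 ± 5.43 and 64.1 ± 12.4 CPM (log2 fold change -1.94, SE 0.28, adjusted p = 0.0439). In B cell-like cells Gstp1 was also lower in celiac libraries than in duodenal replicate 1, so its difference is not special to this class. In resident cDC2-like cells, where it did not pass, its log2 fold change was -2.31 to -1.69 with each library left out in turn. Ighg2b (-9.16) had 99.5% of its duodenal UMIs in 1 barcode, and Iglc2 (-3.30) was the remaining call of 4 among 9690 genes, with 412 at an unadjusted p under 0.05. The B cell list had a median of -1.13 there (fry adjusted p = 0.414, 0 adjusted over the list alone), and Igkc was seen in 99.3% of all cells of duodenal replicate 2. The count was 9 without celiac replicate 1, 0 without celiac replicate 2, 7 without celiac replicate 3, 183 without duodenal replicate 1 and 12 without duodenal replicate 2; DESeq2 called 14.

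Resident cDC2-like cells of celiac nodes had less Bloc1s1, a subunit of the lysosome biogenesis complex, than those of duodenal nodes. It averaged 11.8 ± 2.40 CPM (SD, n = 3) and 47.4 ± 0.496 (n = 2), a log2 fold change of -1.99 (SE 0.26, adjusted p = 0.0278). It was the only gene of 9910 past the threshold, with 357 at an unadjusted p under 0.05 and 4 called by DESeq2. Bloc1s1 had -1.89 in B cell-like cells against duodenal replicate 1, so the difference is not special to this class. The count was 0 without celiac replicate 1 or 2, 5 without celiac replicate 3, 491 without duodenal replicate 1 and 11 without duodenal replicate 2. Of 22 lists in resident cDC1-like cells and 25 in resident cDC2-like cells 0 passed in fry, with 1 and 2 at an unadjusted p under 0.05, and 0 in camera, with 2 and 1. In resident cDC1-like cells 10 of 16 maturation and migration genes passed adjusted over the list alone, with 4 of 16 higher in celiac nodes and a median of -0.71, among them Ccr7 at -1.90. In duodenal replicate 2, which is 1 of the 2 duodenal libraries there, Fscn1 of that list was seen in 79.6% of all cells, against 15.9% in duodenal replicate 1. Cholesterol synthesis genes had 1 of 18 higher there and 2 of 18 in resident cDC2-like cells, with medians of -0.43 and -0.30.

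Monocytes and macrophages of celiac nodes had less Fscn1, Ccl22 and Cacnb3, genes that mature cDC express strongly, than those of duodenal nodes. Fscn1, the actin-bundling protein fascin, averaged 26.5 ± 8.03 CPM (SD, n = 3) in celiac and 381 ± 229 (n = 3) in duodenal libraries (log2 fold change -3.85), and Ccl22 had -3.39, Cacnb3 -3.51, Apol7c -3.57 and Ccl5 -2.94. Fscn1 was seen in 79.6% and 90.7% of all cells of duodenal replicates 2 and 3, so cDC RNA in these libraries is not excluded as the source. In all 30 of 7011 genes passed, 1 higher (Tnip3, 2.42) and 29 lower, with 778 at an unadjusted p under 0.05. Without duodenal replicates 2 and 3 together 9 passed, 4 of them shared. The count was 0 without celiac replicate 2, 2 without celiac replicate 3, 1627 without duodenal replicate 1, 4 without duodenal replicate 2 and 6 without duodenal replicate 3, and 20 without celiac replicate 1. DESeq2 called 99.

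Plasma cells of celiac nodes had less Ighg1 (log2 fold change -9.27) and more Ighv1-11 (6.22) and Clec2g (4.27) than those of duodenal nodes. These were the 3 calls among 6472 genes, with 1118 at an unadjusted p under 0.05, and 135 in DESeq2. The count was 0 without celiac replicate 1, celiac replicate 3 or duodenal replicate 2, 2019 without duodenal replicate 1 and 1 without duodenal replicate 3; without both duodenal replicates 2 and 3 it was 2, 1 of them shared. Ighg1 is also the leading gene of cluster 26, most of which came from duodenal replicate 3. Proliferating cells of celiac nodes had less F13a1 (-6.86), Igha (-4.70) and Lyz2 (-3.64), the 3 calls among 10342 genes, with 534 at an unadjusted p under 0.05 and 19 in DESeq2. That count was 0 without celiac replicate 1 or duodenal replicate 3, 1 without celiac replicate 2 or duodenal replicate 2, 2 without celiac replicate 3 and 160 without duodenal replicate 1. Without both duodenal replicates 2 and 3 it was 3, of which 1 was shared; Igha is a plasma cell gene that lost the threshold in migratory cDC in that setting. Genes of these 2 classes and of the monocytes and macrophages were named after their values were seen.

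Pancreatic acinar and red cell genes led the list of genes higher in migratory cDC of liver replicate 3 than in the other 6 libraries, and 1 barcode held nearly all UMIs of each. The 10 genes with the largest log2 fold changes among those called, Hbb-bs, Cela2a, Cela3b, Ctrb1, Cpb1, Clps, Prss2, Try5, Pnliprp1 and Pnlip, had 91.5% to 99.4% of their liver UMIs in a single barcode. The barcode rich in acinar RNA, a migratory cDC2-like cell, had 5086 acinar UMIs among 14014, and the one rich in red cell RNA, a migratory cDC1-like cell, had 1673 red cell UMIs among 7838. Hbb-bs, Cpb1 and Pnliprp1 had 0 UMIs in the other 6 libraries and were at least 766-fold, 129-fold and 86.2-fold higher, taking 3 counts over those libraries as the floor. With few UMIs elsewhere, the pooled ratio was 640 for Cela2a (176 to 5295), 540 for Cela3b (149 to 4471), 365 for Try5 (100.2 to 3024) and 209 for Pnlip (70.7 to 1019). Hbb-bs, Prss2 and Try5 have near-identical paralogs that can share reads.

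**Figure D4:**
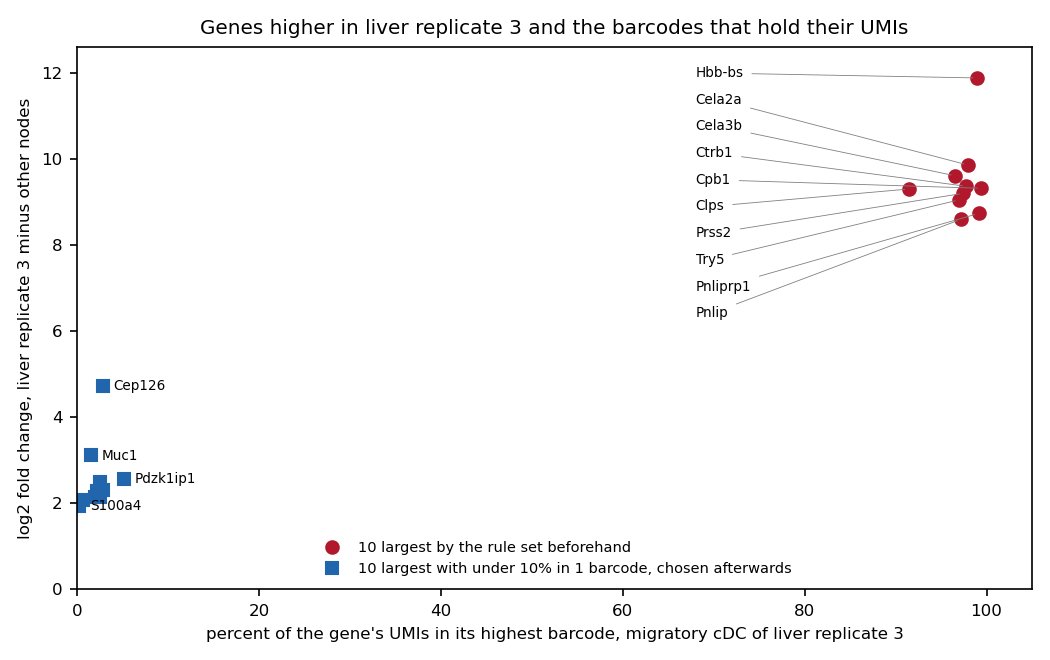
Percent of a gene's UMIs found in the highest barcode of liver replicate 3 against its log2 fold change in migratory cDC, for the 10 genes with the largest fold changes and for the 10 chosen afterwards. The first 10 lie between 91.5% and 99.4%.

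Clps (chromosome 17, 28558149 to 28560766), the colipase of pancreatic juice, stayed higher in migratory cDC of liver replicate 3 without its richest barcodes. With barcodes of at least 10 acinar or red cell UMIs left out, its log2 fold change was 5.59 (SE 0.92). The duodenal libraries then had 0 Clps UMIs, so the size of this fold change rests in part on an empty group. Clps was seen in 38 of 4274 liver cells, against 1 of 1093, 4 of 2334 and 3 of 777 in celiac replicates 1, 2 and 3. The setting called 133 genes, 64 higher and 69 lower, all among the 162 called with these barcodes in.

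Clps was seen more often in migratory cDC1-like than in other cells of liver replicate 3, a comparison chosen after the values were seen. With the same barcodes left out, 29 of 1563 migratory cDC1-like cells had a Clps UMI (1.86%, exact 95% interval 1.25 to 2.65), against 9 of 2711 migratory cDC2-like cells (0.332%, 0.152 to 0.629) and 2 of 2550 B cell-like cells (0.0784%, 0.0095 to 0.283), which should lack it. The median depths were 3152, 3366 and 2194 UMIs. Any gene of the acinar list was seen in 4.10% of these cDC1-like cells (3.17 to 5.20), 0.922% of cDC2-like cells (0.598 to 1.36) and 0.588% of B cell-like cells (0.330 to 0.968). In migratory cDC1-like cells of celiac replicates 1, 2 and 3 Clps was seen in 1 of 608, 3 of 1148 and 2 of 347 cells, and in duodenal replicate 1 in 0 of 339, which allows a share of cells with a UMI of up to 1.08%.

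Il2ra and Muc1, chosen after their values were seen as were the other genes spread over many barcodes, were higher in migratory cDC of liver replicate 3, a lone library, than in the other 6. Il2ra had 1208 UMIs in 806 liver cells and a log2 fold change of 2.07 (SE 0.26), and Muc1 128 UMIs in 123 cells and 3.11 (SE 0.48). Muc1 came to 8.35 CPM in liver replicate 3, against 5.27 in celiac and 0.0719 in duodenal libraries, so most of this fold change comes from the duodenal group. S100a4 had 1.93, Pdzk1ip1 2.55, Ip6k3 2.48, Ckap4 2.31, Pkd2 2.28, Gda 2.15 and Aif1l 2.15, the last no longer past the threshold without the barcodes rich in acinar or red cell RNA. Cep126 had a fitted 4.72 but a pooled ratio of 3.62 (2.44 to 5.41).

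Pla2g7, Ido1 and Serpind1 were lower in migratory cDC of liver replicate 3 than in the other 6 libraries. Pla2g7 had 52 liver UMIs against 3175 in the others (log2 fold change -5.12, SE 0.61, adjusted p = 5.5e-05), and Ido1 had -3.74 (SE 0.47, adjusted p = 0.000117). Serpind1, the thrombin inhibitor heparin cofactor II, had 1 liver UMI against 109, a pooled ratio of 0.0201 (0.000504 to 0.114), and Lilra5 1 liver UMI at a ratio of 0.0365 (0.000909 to 0.211). Ppp1r1a (-4.35), Tnik (-3.97), Syngr3 (-3.76), Sh3gl3 (-3.74), Pcdh1 (-3.71) and Fndc5 (-3.61) were lower as well. Of the 2713 migratory cDC2-like cells of liver replicate 3, 2703 lay in cluster 6, while celiac and duodenal cells also fill cluster 15, for which Pla2g7 is a leading gene by 1 of the 2 definitions used. Ccr7 (-0.90), Aldh1a2 (-0.74), Itgae (-1.57) and Cd274 (-0.60) did not pass.

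In all 162 of 11732 genes passed in the liver contrast, 92 higher and 70 lower, with 1093 at an unadjusted p under 0.05 and 82 in DESeq2. Liver replicate 3 is a lone library, assumed to vary like the others, and 158 of the 162 genes lay outside the range of the other 6. The count was 81 without celiac replicate 2, 484 without duodenal replicate 1 and 249 without duodenal replicate 2. It was 522 without both duodenal replicates 2 and 3, and 0 when thinned to the smallest library. Against the celiac libraries alone 44 genes passed.

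RNA of other organs and cell types in migratory cDC is given in this paragraph as CPM of the library total, without TMM scaling. The acinar list came to 1.97 ± 1.01 CPM in celiac and 0.392 ± 0.368 in duodenal libraries (SD, n = 3 each), and 354 in liver replicate 3. There 1 barcode held 5086 acinar UMIs, and 179 remained in 4274 cells without the barcodes rich in acinar or red cell RNA. The hepatocyte list came to 28.1 ± 3.97, 13 ± 3.13 and 48.1 CPM; it includes Trf, transferrin, which many cells make. The enterocyte list came to 6.29 ± 0.348, 5.46 ± 5.88 and 12.7 CPM, and the islet list to 0 in all 7 libraries. The B cell list came to 225 ± 120, 789 ± 368 and 136 CPM and the T cell list to 175 ± 42.0, 329.6 ± 191 and 109.7 CPM.

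The authors' deposited table of 8 cell clusters, from a set of cells the labels do not name, matched 3 clusters found here by its mean expression. Its clusters 0 and 1 were nearest to migratory cDC2-like cluster 6, clusters 2, 3, 4 and 6 to migratory cDC1-like cluster 4, and clusters 5 and 7 to cluster 12, with rank correlations of 0.92 to 0.99 across 6375 genes, which are not independent replicates. The authors' cluster 6 had the lowest, 0.920, with 0.890 for migratory cDC2-like cluster 6; Cd40, Ccl22 and Ccl17 led it and its mean Sirpa (0.169) was above its mean Xcr1 (0.00669), so its match is unsure. In that table Aldh1a2 marked cluster 7 (1.80 in the deposited log2 scale), Fabp5 (2.32) and S100a4 (1.99) marked cluster 1, and Ccr7 (1.96) marked cluster 3. Mean Malat1, a nuclear RNA, was 28.4 and 11.7 in the authors' clusters 5 and 7, against 477 to 1287 in their others. Cluster 12 found here, the nearest to both, had a median of 903 genes per cell, so the quality of these cells is unsure.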

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

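Chosen only after the result was seen were the tests of free RNA in duodenal replicates 2 and 3, of B cell-like cells, of barcodes rich in acinar RNA, and of other splits for gene counts, as was the requirement that an interval lie clear of its bound. Acinar RNA in migratory cDC2-like cells had been seen before any of its tests were written, and the value over genes past the count filter in B cell-like cells was added after the unfiltered one.

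Tnfsf9, Fabp5, Ccrl2 and Tnfaip2 drew attention because the difference between celiac and duodenal nodes was itself different in migratory cDC1-like and cDC2-like cells, by an interaction test (edgeR, library as a block). The log2 effects differed by -2.60 for Tnfsf9, -1.69 for Fabp5, 1.40 for Ccrl2 and 1.39 for Tnfaip2, and with each library left out in turn they stayed within -3.03 to -2.39, -1.80 to -1.55, 1.33 to 1.41 and 1.21 to 1.98. The effect on Tnfsf9 came to -0.97 in cDC1-like cells, short of the threshold, and to 1.82 in cDC2-like cells, past it. Most celiac cDC2-like cells lay in cluster 6, of which Fabp5 is the leading gene, and most duodenal ones in cluster 15, so these tests leave open a different mix of clusters. Liver replicates 1 and 2 drew attention as data no comparison uses: their barcode lists hold 10550 and 11396 cells, above the 9320 of the largest celiac or duodenal library.

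The 44 genes called between celiac and duodenal migratory cDC form the first pattern weighed, and they part into 8 immunoglobulin and B cell genes and 36 others. For the 8, free RNA in duodenal replicates 2 and 3 may account for most of the difference: without both libraries their median log2 fold change kept 0.318 of its size. For the other 36, such as Smox, Muc1 and Pla2g7, the median kept 0.942 and 36 of 36 kept at least 50% of their size. Their difference was thus also present against duodenal replicate 1 alone. These genes were called with that library in the fit, which favours genes that differ in it, so the kept share does not exclude that source. A preparation difference that runs through whole duodenal libraries stays open, as the same genes moved by 0.427 of their size in B cell-like cells over 18 genes past the count filter, and by 0.626 over 35 without the filter. Different shares of clusters 6 and 15 stay open too, with 0.508 of the size left within cluster 15 and cluster 6 too small to test, and so does a true difference between the nodes, which was not tested.

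Acinar RNA such as Clps, Cela2a and Ctrb1 in migratory cDC2-like cells of liver replicate 3 is the second pattern. Free RNA spread over the suspension is argued against for the bulk of it: 99.0% of the acinar UMIs lay in 1 barcode that held 0.144% of the class's UMIs. That share was not part of the prediction, which rested on the ratio of acinar UMIs per migratory cDC2-like to B cell-like cell. The ratio, 12, had too wide an interval (0.0405 to 534) to tell. For the other cells with an acinar UMI free RNA stays open. The 3 highest barcodes held 99.4%, so a few droplets with an acinar cell or its contents are a candidate explanation; the richest had 14014 UMIs, 4.25 times the median of migratory cDC there. Across the class doublets cannot be told apart from other sources by depth, since the 27 cells with an acinar UMI, the richest barcode among them, had 1.18 times the median UMIs of the others, 3967 against 3360. That ratio is under the 1.2 set in advance, but its interval of 0.99 to 1.42 spans that bound. No biological explanation, such as uptake of pancreas tissue by cDC, was tested.

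The 6 libraries can be split into 3 and 3 in 10 ways, the real one included, too few for a share under 0.05. In migratory cDC 1 of the 10 splits, the real one, gave 44 genes, and the highest other gave 0. Monocytes and macrophages gave 30 genes against 0 and proliferating cells 3 against 0, each with 1 split as large. Plasma cells gave 3 in 2 splits, the other of which set celiac replicate 1 with duodenal replicates 2 and 3. For gene lists in migratory cDC 10 of 10 splits gave as many as the real 0, and the highest other gave 1.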

How the results depend on the processing

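The alternatives without both duodenal replicates 2 and 3, with a fixed doublet rate, of single clusters, of liver against celiac libraries alone and without certain barcodes were tests chosen after the data were seen; the others were planned. Of the counts of calls and the shares of cDC classes, 108 stayed, 77 moved and 1 reversed. With 1 library left out 68 stayed and 43 moved. A count stayed if it lay within 1.5 times the reported one, whichever genes were called. A share stayed if it kept its sign, whatever its size, so no share could be counted as moved. Of the values of single genes and the shares of other classes, 1038 kept direction and side of the threshold, 148 lost the threshold, 40 gained it and 39 reversed; with 1 library left out these were 466, 109, 14 and 40. The cause was not tested except where named.

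With each library left out in turn the number of genes called ranged from 2 to 1252 in migratory cDC, 5 to 806 in migratory cDC1-like, 0 to 409 in migratory cDC2-like, 0 to 183 in resident cDC1-like and 0 to 491 in resident cDC2-like cells. It ranged from 0 to 1627 in monocytes and macrophages, 0 to 2019 in plasma cells, 0 to 160 in proliferating cells, 32 to 101 in the interaction and 81 to 484 in the liver contrast. Most of the highest counts came without duodenal replicate 1, which is the largest duodenal library. What then remained of the duodenal group was replicate 2, with or without replicate 3. Igkc was seen in 99.3% and 100% of the cells of those replicates, against 62.3% in replicate 1. Gene lists gave 0 to 1 in migratory cDC2-like and in resident cDC1-like cells.

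Without a filter on low counts the calls were 280 in migratory cDC, 107 in migratory cDC1-like, 243 in migratory cDC2-like, 120 in resident cDC1-like, 66 in resident cDC2-like, 359 in monocytes and macrophages, 702 in plasma and 172 in proliferating cells, 181 in the interaction and 370 in the liver contrast. This setting shifted the median of all genes by up to 0.115 in migratory cDC1-like and -0.214 in plasma cells. DESeq2 called 26, 62, 14, 4, 99, 135, 19 and 82 in migratory cDC1-like, migratory cDC2-like, resident cDC1-like, resident cDC2-like, monocyte and macrophage, plasma and proliferating cells and the liver contrast. RLE scaling gave 3 in resident cDC2-like cells, and in migratory cDC 19 higher and 39 lower.

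A block for the replicate number, which assumes pairs, gave 163 in migratory cDC, 73, 126, 48 and 24 in migratory cDC1-like, migratory cDC2-like, resident cDC1-like and resident cDC2-like cells, 32 in proliferating cells and 103 in the liver contrast, and 0 for the interaction in place of its library block. Same-number libraries correlated at 0.058, 0.138 and -0.046, so not every pair passed the 0.1 required, and celiac replicate 3 correlated best with duodenal replicate 1. That check was computed after the blocked counts were seen. T cell-like cells made up 34.1% of celiac replicate 1 and 37.7% of duodenal replicate 1, against at most 7.61% in replicates 2 and 3 of either node. A preparation shared by libraries of the same number is therefore not excluded.

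Resolution 0.5 gave 5 in migratory cDC, 0 in migratory cDC1-like, resident cDC1-like and resident cDC2-like cells and 1 in proliferating cells, and resolution 2 gave 14 in migratory cDC1-like and 0 in resident cDC2-like, monocyte and macrophage and proliferating cells. With doublets kept, 0 passed in resident cDC1-like, monocyte and macrophage and proliferating cells and 2 in resident cDC2-like cells. A fixed doublet rate gave 14, 23, 12, 3, 5 and 0 in migratory cDC1-like, migratory cDC2-like, resident cDC1-like, resident cDC2-like, plasma and proliferating cells.

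Looser cell filters gave 20 in migratory cDC, 13, 47 and 0 in migratory cDC1-like, migratory cDC2-like and resident cDC1-like cells and 0 in proliferating cells; resident cDC2-like cells could not be compared under them. A 5% mitochondrial limit gave 9, 0, 8, 0 and 5 in migratory cDC, migratory cDC1-like, migratory cDC2-like, resident cDC1-like and monocyte and macrophage cells. All 7 libraries in the fit gave 69 in migratory cDC, 0 in resident cDC1-like cells and 14 in monocytes and macrophages. Thinning to the smallest library gave 2 in migratory cDC, 14, 39, 7 and 3 in migratory cDC1-like, migratory cDC2-like, resident cDC1-like and resident cDC2-like cells, and 0 in plasma cells and the liver contrast.

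Without both duodenal replicates 2 and 3, where fewer samples remain and the lone duodenal library is assumed to vary like the celiac ones, the calls were 136 in migratory cDC, 204 in migratory cDC2-like, 12 in resident cDC1-like, 11 in resident cDC2-like cells, 9 in monocytes and macrophages, 101 in the interaction and 522 in the liver contrast, with 1 gene list in migratory cDC2-like cells. Clusters 4 and 15 alone called 0. Liver against celiac libraries alone called 44.

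The fixed markers that reversed were not past the threshold. In migratory cDC Xcr1 came to -0.00725 at the 5% mitochondrial limit, Cd274 to -0.0148 under looser filters and -0.51 without duodenal replicates 2 and 3, and Itgax to 0.0166 by DESeq2, 0.0118 without the count filter and 0.00597 with the block. In migratory cDC1-like cells Xcr1 came to -0.0506 with the block and -0.0494 thinned, Sirpa to 0.0613 by DESeq2, 0.370 with the block, 0.0214 at resolution 0.5 and 0.00257 at the 5% limit, and Cd274 to 0.0617 thinned. In migratory cDC2-like cells Sirpa came to 0.0117 with the block, Cd274 to 0.0601 with doublets kept and 0.0750 in cluster 15, and Itgax to -0.0449 and -0.0108 at resolutions 0.5 and 2, -0.0558 with doublets kept, -0.119 under looser filters, -0.0450 at the 5% limit and -0.209 without both duodenal replicates. In resident cDC1-like cells Itgae came to -0.000816 by RLE, -0.000441 by DESeq2, -0.257 with the block, -0.0341 at resolution 0.5, -0.0275 at the fixed doublet rate and -0.0256 without both duodenal replicates. Cd274 came to 0.332 there with the block, and Itgax to -0.0118 at resolution 0.5 and -0.107 without both. In resident cDC2-like cells Sirpa came to 0.0246 without the count filter, 0.0684 with the block, 0.00524 at resolution 0.5 and 0.0437 thinned, and Cd274 to -0.165 without both. In the liver contrast Sirpa came to 0.0266 against celiac alone and Itgax to 0.00694 without the count filter.

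With 1 library left out, log2 fold changes in migratory cDC ranged from -0.58 to 0.000742 for Ccr7, -0.0697 to 0.67 for Xcr1, -0.17 to 0.59 for Cd274 and -0.16 to 0.27 for Itgax. In migratory cDC1-like cells Sirpa ranged from -0.67 to 7.16, Itgae from -1.11 to 0.31 and Cd274 from -0.34 to 0.15, and in migratory cDC2-like cells Sirpa from -0.30 to 0.0620, Cd274 from -0.64 to 0.48 and Itgax from -0.21 to 0.67. In resident cDC1-like cells Itgae ranged from -0.22 to 0.19, Cd274 from -0.61 to 1.97 and Itgax from -0.11 to 0.42, and in resident cDC2-like cells Sirpa from -0.27 to 0.48, Cd274 from -0.17 to 1.31 and Itgax from -0.21 to 0.13. In the liver contrast Sirpa ranged from -0.16 to 0.0111 and Itgax from -0.11 to 0.14.

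Differences in shares of all cells, celiac minus duodenal in percentage points, ranged from -0.525 to 1.01 for NK and innate lymphoid cells, -8.02 to 13.8 for T cells and -3.99 to 0.293 for plasma cells with 1 library left out. T cells came to -0.503 at the 5% mitochondrial limit. Resident cDC1-like cells came to -4.07 among cDC-like cells, where the denominator holds only the 4 cDC-like classes and cluster 14, against 5.29 over all cells.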

Other observations

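No test of this part was planned: its values were picked after they were seen, and they are given without explanation.

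In liver replicate 3, without the barcodes rich in acinar or red cell RNA, Clps was seen in 1 of 678 resident cDC1-like cells, in 0 of 754 resident cDC2-like cells and in 1 of 958 T cell-like cells. Their medians were 7120, 3671 and 2397 UMIs. The 0 of 754 allows a share of cells with a UMI of up to 0.488%, the upper limit of its exact 95% interval, and sets no limit on cells with Clps RNA that was not caught. In duodenal replicate 1 Clps was seen in 0 of 2265 B cell-like and 0 of 3050 T cell-like cells, with upper limits of 0.163% and 0.121%.

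Genes of the acinar list were seen in 1.33% of resident cDC1-like cells of liver replicate 3 (0.609 to 2.51) and in 0.939% of its T cell-like cells (0.431 to 1.78). In T cell-like cells of celiac replicate 1 and duodenal replicate 1, 0.597% (0.335 to 0.983) and 0.426% (0.227 to 0.728) had a UMI of the list.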
